A study of Mus musculus with 6 samples.

How the data were processed

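RNA was measured in 6 mouse tumours of a transplantable high-grade serous ovarian cancer model, 3 from animals given AZD7507 and 3 from animals given vehicle. Per the labels' protocols, a mouse cell line was injected into the abdominal cavity and tumours were left to establish for 21 days. Carboplatin was then given in 3 weekly cycles, AZD7507 followed by daily gavage for 84 days, and tumours were taken at the humane endpoint. That endpoint may fall on different days and no day of collection entered the analysis, so time cannot be told apart from treatment. Libraries were made from total RNA after depletion of ribosomal RNA, per the labels' protocols. The protocols also mention healthy omentum, which is not analysed here.

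The deposited table holds 16344 Ensembl genes in 6 libraries. Its values are log2 RPKM (read density scaled by gene length and library size) that the authors normalized with cqn, as the name of the deposited table says. The cqn method adjusts for gene length and GC content and can equalise the distributions of the libraries. In the deposited log2 values the upper quartile was 3.52 and the maximum was 10.16 in each library, while the medians were 2.32. BWA 0.7.15-r1140 and HTSeq are named in the submitters' processing notes, as are the builds mm10 and GRCm38. The annotation release, the strand setting and the filter on low genes were not given in the sources used here. A gene that a few libraries hold in great amount can shift the other values of a library after such normalization, and a global change in RNA content cannot be seen in these values.

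No read counts entered the analysis, so the depth behind each value is unknown, and no counting interval or detection floor is given. Precision therefore comes only from the spread between the 3 tumours of each group. Values below 0 on the log2 scale lie under 1 RPKM and may rest on few reads.

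Gene symbols were matched for 16306 of the 16344 identifiers. Coordinates are those of GRCm38 in the GENCODE M21 annotation, which may not be the authors' release. Groups were taken from the treatment label, and replicates were numbered in the order of their records. The labels pair no samples across groups and name no batch. The design text speaks of 3 against 3 mouse tumours but gives no animal for a tumour, so the p-values measure the spread between these tumours only.

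The log2 values were tested as deposited, with no pseudocount and no filter, using limma 3.58.1 in R 4.3.3 with a trended and robust variance prior. The Benjamini-Hochberg adjusted p threshold was 0.05, 2-sided. Differences are AZD7507 minus vehicle. Before the data were examined, 32 gene lists with 384 distinct genes were fixed, and 298 of these genes had a value. The 28 lists with at least 3 measured members were tested with limma's camera at a preset correlation of 0.01 between genes. Named genes followed a rule fixed at the same time. It took, per direction, up to 10 genes with the largest change among those past the threshold with groups that did not overlap, leaving out models named Gm plus digits or ending in Rik. Where fewer than 10 passed, genes with the smallest unadjusted p filled the places and are said not to pass. Csf1r, Csf1 and Il34 were always taken, and 3 members with the smallest unadjusted p came from each list. A gene that this rule took is not reported here. Other genes named in the text were chosen after their values were seen.

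Alternatives were a constant variance prior, a minimum mean log2 RPKM of 0, pseudocounts of 1 and 0.1, quantile normalization, median centring, limma array weights, and leaving out each library in turn. For lists, camera with an estimated correlation and limma's directional fry were also run. With an estimated correlation camera also bases its degrees of freedom on the few libraries rather than on the genes. A call lost there need not come from correlation between members. An acinar score as covariate, a fit without both acinar-rich libraries, and an estimated correlation in these and in each fit without 1 library were added after the data had been seen. The fits were tested on simulated data with 200 changed genes among 16344. Of 50 genes each, 36% were called at a log2 change of 1, 76% at 2, 86% at 3 and 98% at 4. The same simulated comparison called 6 of 16144 unchanged genes. Its noise was independent between genes, with SDs taken from these libraries. It held no correlation between genes and no shared outlying library, so these rates may not hold for the real data.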

Results

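The series asked what the CSF1R inhibitor AZD7507 did to the transcriptome of ovarian tumours that had relapsed after carboplatin. CSF1R is the receptor for the growth factors CSF1 and IL-34, on which macrophages depend. The 3 AZD7507 and 3 vehicle libraries held log2 RPKM values for 16344 genes. The depth of each library is unknown. Values are given as mean ± SD with n = 3 in each group unless stated.

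Macrophage transcripts were lower in the AZD7507 tumours. Csf1r, the drug target, was at a log2 RPKM of 4.97 ± 0.45 with vehicle and 2.35 ± 0.56 with AZD7507, and fell by 2.62 (SE 0.32), which was 6.14-fold lower. The complement C1q genes C1qa, C1qb and C1qc, which macrophages make, fell by 2.56, 2.37 and 2.66, and Adgre1, which encodes a surface marker of mouse macrophages, fell by 2.28. Across the transcriptome 55 genes fell and 3 rose (limma, Benjamini-Hochberg adjusted p under 0.05), while at an unadjusted p under 0.05 there were 898 lower and 541 higher. The groups did not overlap for 2511 genes, or 15.4%, where chance gives 10%.

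Csf1r lies on chromosome 18 of GRCm38 at 61100598 to 61132149 on the plus strand and is a protein-coding gene. Its vehicle libraries were at 4.85, 5.47 and 4.59 and its AZD7507 libraries at 2.57, 2.78 and 1.71, with an adjusted p from limma of 0.035. The ligand genes did not pass. Csf1 was at 4.82 ± 0.41 with vehicle and 4.92 ± 0.04 with AZD7507, a difference of 0.10 (SE 0.20, limma adjusted p 0.93). Il34 was at 0.58 ± 0.59 and 0.91 ± 0.17, a difference of 0.33 (SE 0.30, limma adjusted p 0.83).

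**Figure D1:**
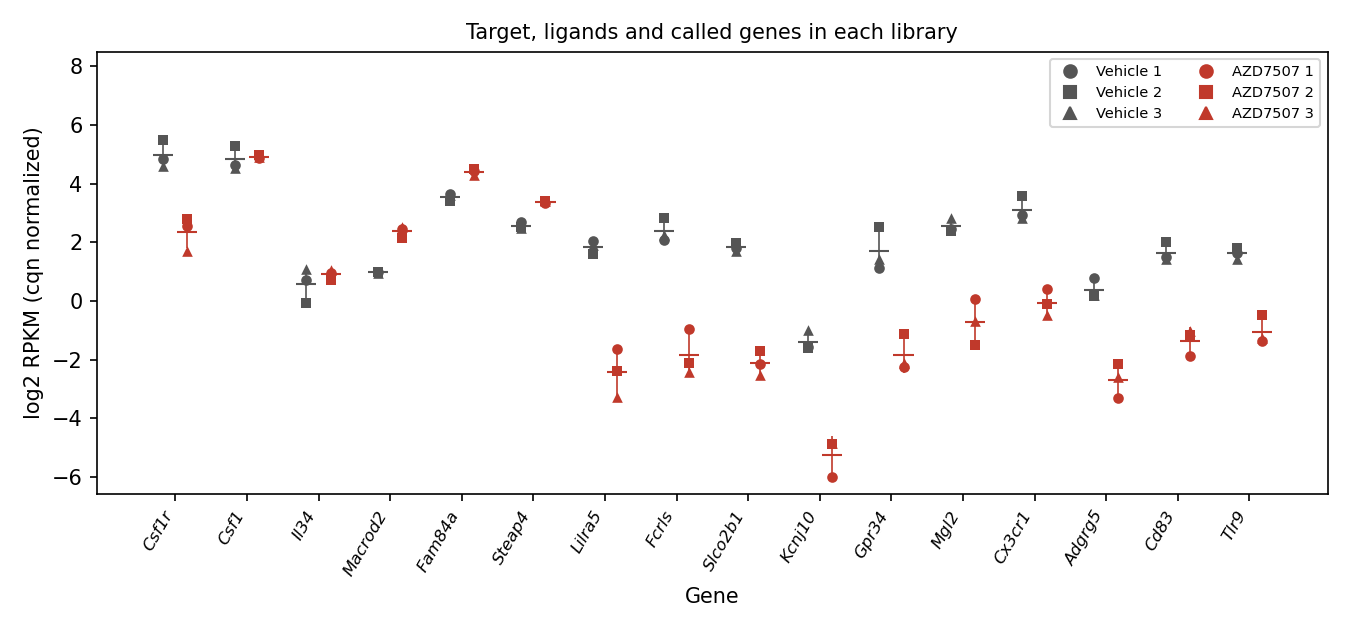
Log2 RPKM of the drug target, its ligands and the called named genes in each library, with vehicle in grey and AZD7507 in red. Points are libraries, horizontal lines are group means and vertical lines are SDs (n = 3); Csf1r lies at 4.59 to 5.47 with vehicle and at 1.71 to 2.78 with AZD7507.

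The named genes with the largest falls were Lilra5 and Fcrls, both immunoglobulin-like receptors of myeloid cells. Lilra5 (chromosome 7, 4237754 to 4243463) went from 1.83 ± 0.22 to -2.43 ± 0.81, a change of -4.27 (SE 0.41, limma adjusted p 0.021). Fcrls (chromosome 3, 87250758 to 87263738) went from 2.38 ± 0.41 to -1.84 ± 0.76, a change of -4.22 (SE 0.41, limma adjusted p 0.021). Slco2b1, an organic anion transporter gene on chromosome 7 at 99657804 to 99711340, changed by -3.95 (SE 0.27) with an adjusted p of 0.011 from limma. The potassium channel gene Kcnj10 changed by -3.86, but its AZD7507 mean of -5.25 lay near the lowest values of the table. Gpr34 fell by 3.52, the lectin gene Mgl2 by 3.28, the fractalkine receptor gene Cx3cr1 by 3.18, Adgrg5 by 3.07, Cd83 by 3.00 and the DNA sensor gene Tlr9 by 2.67. Means with AZD7507 were below 0 for each of these 10 genes, so their folds rest on low values. With a pseudocount of 1 the differences were -1.93 for Lilra5, -2.26 for Fcrls, -1.88 for Slco2b1 and -0.43 for Kcnj10, against -2.40 for Csf1r, so the order of the genes changed. Kcnj10 and Gpr34 then no longer passed (limma adjusted p 0.086 and 0.060).

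Genes outside the naming rule that fell, chosen after their values were seen, included Apoe, which encodes a lipid carrier. It was at 8.62 ± 0.10 with vehicle and 7.06 ± 0.18 with AZD7507, a change of -1.55 (SE 0.14). Stab1, a scavenger receptor gene, fell by 2.25, Hpgds, a prostaglandin D2 synthase gene, by 2.62, and Cd33, a sialic acid binding receptor gene, by 2.55. Of the 58 called genes, 7 were models without a proper symbol. Lilra5, Pirb and Mgl2 belong to families of similar genes, so reads may have been split between their members.

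The 3 genes that rose were Macrod2, Fam84a and Steap4. Macrod2, an ADP-ribose hydrolase gene on chromosome 2 at 140395310 to 142392970, went from 0.97 ± 0.03 to 2.38 ± 0.20, a change of 1.41 (SE 0.15, limma adjusted p 0.021). Fam84a changed by 0.85 (SE 0.11) and Steap4, a metalloreductase gene, by 0.82 (SE 0.10), with limma adjusted p of 0.040 and 0.035. Genes that filled the upward places without passing were Iigp1, an interferon-inducible GTPase gene, at a difference of 1.71, Il10 at 1.09, Lhx6 at 0.94, Ptprn at 0.93, Wwc1 at 0.77, Aldh18a1 at 0.68 and Ccn4 at 0.52. Their limma adjusted p ran from 0.072 for Iigp1 to 0.14 for Il10.

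The gene calls depended on having all libraries. With limma, no gene rose when any 1 library was left out (against 3), and the number that fell was 0 without Vehicle 1, Vehicle 2 or Vehicle 3, 14 without AZD7507 1, 1 without AZD7507 2 and 2 without AZD7507 3. Unadjusted p under 0.05 then held for 257 to 1082 higher and 606 to 1359 lower genes.

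Of the macrophage list, 18 of 18 measured members had a negative difference and the mean was -1.85 on the log2 scale. The list fell (camera adjusted p 1.1e-29 with the preset correlation), a call that was lost with an estimated correlation, where the adjusted p = 0.39, and with fry, where the adjusted p = 0.052. Among its members 6 fell when adjusted over all genes, namely Csf1r, Cx3cr1, C1qa, C1qb, C1qc and Adgre1, and 17 when adjusted over the list alone. Members that did not pass over all genes included Lyz2, a lysozyme gene, at 7.76 ± 0.45 and 6.10 ± 0.83, the mannose receptor gene Mrc1 at 4.10 ± 0.57 and 1.97 ± 0.95, Cd68 at 4.25 ± 0.41 and 3.35 ± 0.26, and Trem2 at 3.68 ± 0.26 and 2.98 ± 0.40. The macrophage list held 6 of the 55 lower genes among its 18 members, against 49 among the 16326 other genes (Fisher's exact test, 2-sided, p = 2.0e-11, over genes, which are not independent replicates). The mean log2 level of the list was 4.19 ± 0.39 with vehicle and 2.34 ± 0.48 with AZD7507.

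The list of the CSF1R axis fell by a mean of 0.86 (camera adjusted p 0.0033; adjusted p = 0.39 with an estimated correlation). It shares Csf1r with the macrophage list, and Csf1r was its 1 member that fell over all genes, against 4 adjusted over the list alone. The myeloid transcription factor gene Spi1 differed by -1.39, and the cytokine receptor gene Csf2ra by -0.62, without passing. Csf2rb, of the same receptor, was at 2.62 ± 0.31 with vehicle and 1.62 ± 0.46 with AZD7507. The list of resident-type macrophages did not pass (mean -0.92, camera adjusted p 0.13, 6 of 10 members measured), with differences of -1.52 for F13a1 and -1.37 for Lyve1, and 0 calls over all genes or adjusted over the list alone. Without Vehicle 2, which was highest for this list, the mean was -0.41. Folr2 was at -0.10 ± 1.27 with vehicle and -2.10 ± 1.23 with AZD7507.

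**Figure D2:**
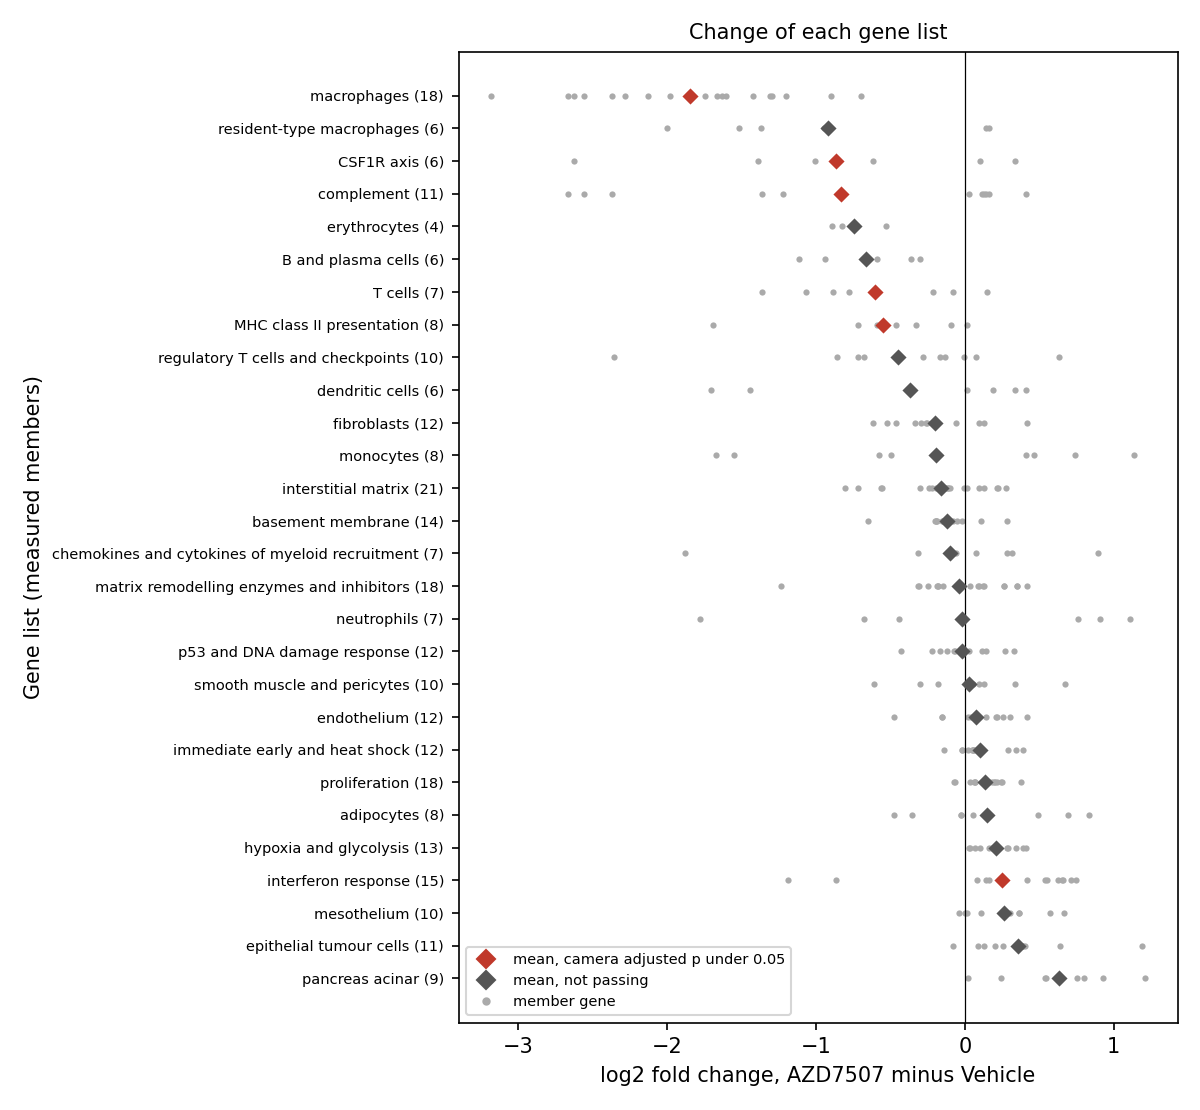
Log2 fold change of AZD7507 minus vehicle for the 28 tested gene lists, with the number of measured members in brackets. Grey dots are genes and diamonds are list means, red where camera with the preset correlation passed; the macrophage list lies lowest at -1.85.

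Complement genes split. The list fell by its mean of -0.83 (camera adjusted p 0.0033; adjusted p = 0.41 with an estimated correlation), while its median was 0.03, of the opposite sign. C1qa, C1qb and C1qc, shared with the macrophage list, were its 3 called members, and 5 were called adjusted over the list alone. The receptor genes C3ar1 and C5ar1 differed by -1.36 and -1.22 without passing. C3, the central complement component, was at 8.62 ± 0.34 with vehicle and 8.73 ± 0.22 with AZD7507, and C4b and C1s1 differed by 0.16 and 0.03. Without both acinar-rich libraries, described below, the complement call was lost (adjusted p 0.11).

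Genes of MHC class II antigen presentation fell as a list (mean -0.55, camera adjusted p 0.0051; adjusted p = 0.60 with an estimated correlation), with 7 of 8 measured members below 0. No member passed over all genes and 1 did adjusted over the list alone. H2-Ob differed by -1.69, H2-Aa by -0.72 and H2-DMa by -0.46. Without Vehicle 1 the list's mean was -0.29 and its camera adjusted p was 0.097.

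T cell genes fell as a list (mean -0.60, camera adjusted p 0.017, or adjusted p = 0.56 with an estimated correlation), with 6 of 7 measured members below 0. Only 7 of its 14 genes were measured, and its mean log2 level was low, at -1.04 ± 0.27 with vehicle and -1.64 ± 0.30 with AZD7507. At the minimum mean log2 RPKM of 0 too few members remained for a test. No member passed over all genes and 2 did adjusted over the list alone. Cd4 differed by -1.36, Cd5 by -1.07 and Il7r by -0.78. The call was lost without Vehicle 2 (adjusted p 0.23), without AZD7507 1 (0.063) and without both acinar-rich libraries (0.30).

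Interferon response genes were the list that rose (mean 0.25, camera adjusted p 0.046; adjusted p = 0.65 with an estimated correlation), with 13 of 15 members above 0. No member passed, either over all genes or adjusted over the list alone. The ubiquitin-like modifier gene Isg15 differed by 0.66 and the GTPase gene Gbp2 by 0.75. The call was lost without Vehicle 2 (mean 0.08, adjusted p 0.23) and without AZD7507 3 (mean 0.08, adjusted p 0.36). With an estimated correlation 0 of the 6 list calls held, with 3 lower lists at an unadjusted p under 0.05. With directional fry 0 held, with 5 lower lists. The mixed test of fry, which ignores direction, gave adjusted p 0.012 for the macrophage, CSF1R axis and complement lists and 0.0058 for T cells. It gave 0.51 for MHC class II and 0.55 for interferon response.

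Other leukocyte lists did not pass with all libraries. B and plasma cell genes passed downward without Vehicle 1 (mean -0.84, adjusted p 0.026) and without AZD7507 1 (mean -1.05, adjusted p 0.0046) at the preset correlation. Both calls were lost there with an estimated correlation (adjusted p = 0.45 and adjusted p = 0.57). The mean of the B and plasma cell list shrank to -0.10 without both acinar-rich libraries. Neutrophil genes had a mean difference of -0.02, with -0.68 for Csf3r, 1.11 for Cxcr2 and -0.44 for Il1b. That list also holds Mmp9, which differed by -1.78, was at 5.94 in Vehicle 2 and is treated below as an osteoclast gene. Monocyte genes had a mean of -0.19, in which the chemokine receptor gene Ccr2 differed by -1.67, Itgam by -1.55 and Chil3 by 1.14. Without passing, the B and plasma cell list had a mean of -0.66, with -0.94 for Cd79b, -1.11 for Bank1 and -0.59 for Jchain. In the dendritic cell list the mean was -0.37 and the median 0.10, and Irf8, a transcription factor gene of dendritic cells and macrophages, fell by 1.71, while Itgax and Batf3 differed by -1.44 and 0.34. The regulatory T cell and checkpoint list had a mean of -0.45 and a median of -0.22. Its mean was 0.081 at the minimum mean log2 RPKM of 0. Havcr2 differed by -2.35 (limma adjusted p 0.053), Cd274 by 0.64 and Il2ra by -0.68. In the list of myeloid recruitment factors Ccl12 fell by 1.88, whereas Cxcl5 and Ccl2 differed by 0.89 and 0.32, and the mean was -0.10 with a median of 0.08. Adjusted over the list alone, 1 monocyte, 2 dendritic cell, 1 checkpoint and 1 recruitment gene fell, and 0 neutrophil or B and plasma cell genes.

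Tumour, stroma and tissue lists did not pass with all libraries, and some passed without 1 of them. Epithelial genes passed upward without Vehicle 3 (mean 0.41, adjusted p 0.0055) and without AZD7507 1 (mean 0.48, adjusted p 0.041), and mesothelial genes without Vehicle 1 (mean 0.40, adjusted p 0.0052) and without AZD7507 2 (mean 0.38, adjusted p 0.016), all at the preset correlation. With an estimated correlation in the same fits the epithelial list had adjusted p = 0.41 and adjusted p = 0.64, and the mesothelial list adjusted p = 0.45 and adjusted p = 0.56. The mesothelial mean shrank to 0.069 without Vehicle 2, and the epithelial mean to 0.24 without Vehicle 1. Without Vehicle 1, interstitial matrix (mean -0.29, adjusted p 0.0067) and fibroblast genes (mean -0.33, adjusted p 0.034) passed downward at the preset, but each had adjusted p = 0.45 with an estimated correlation. Without Vehicle 2 the means of these lists were only -0.010 and -0.032. With all libraries, epithelial genes had a mean of 0.36 (camera adjusted p 0.066), with 0.41 for Krt18, 0.39 for Krt8 and 1.19 for Cldn3. Mesothelial genes had a mean of 0.26, with 0.67 for Gpm6a and 0.37 for Upk3b, and Rspo1 was at 0.36. Interstitial matrix genes had a mean of -0.16, with Col12a1 at -0.81, Fbn1 at -0.56 and Bgn at -0.19. The basement membrane mean was -0.12, with Hspg2, Lama5 and Lama4 at -0.20, -0.20 and -0.19. Fibroblast genes had a mean of -0.20, with Mfap5 at -0.52, Pi16 at -0.61 and Pdgfrb at -0.46. Matrix remodelling genes had a mean of -0.04 and a median of 0.06, with Ctsb at -0.18, Ctsk at -1.24 and Adamts1 at 0.27. Without both acinar-rich libraries their mean turned to 0.29 and passed at the preset (camera adjusted p 0.024), a call lost with an estimated correlation. The Ctsk difference came from Vehicle 2, at 6.45 against 2.39 to 2.93 in the other libraries, and was 0.012 without it. In the smooth muscle and pericyte list, the mean was 0.03 while the test pointed down; Cspg4 differed by -0.61, Actg2 by 0.67 and Notch3 by -0.18. Endothelial genes had a mean of 0.08, with Cldn5 at -0.47, Esam at 0.41 and Kdr at 0.30, and adipocyte genes a mean of 0.15, with Lpl at 0.49, Acsl1 at -0.47 and Cfd at 0.84. None of these lists had a member that passed, over all genes or adjusted over the list alone.

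Lists of cell state did not pass with all libraries either. Hypoxia and glycolysis genes passed upward without Vehicle 2 (mean 0.33, adjusted p 0.0056), without AZD7507 2 (mean 0.38, adjusted p 0.0017) and without both acinar-rich libraries, described below (mean 0.50, adjusted p 1.8e-05), all at the preset correlation. With an estimated correlation in these fits, adjusted p = 0.65, adjusted p = 0.56 and adjusted p = 0.67. The mean of the hypoxia and glycolysis list shrank to 0.031 without Vehicle 1. Proliferation genes passed upward without Vehicle 2 (mean 0.31, adjusted p 0.00033), without AZD7507 1 (mean 0.25, adjusted p 0.0033) and without both acinar-rich libraries (mean 0.27, adjusted p 0.0037) at the preset. With an estimated correlation these had adjusted p = 0.65, adjusted p = 0.64 and adjusted p = 0.67. Without Vehicle 1 the proliferation mean was only 0.045. Erythrocyte genes passed downward without Vehicle 1 (mean -1.26, adjusted p 0.0012) and without AZD7507 2 (mean -1.05, adjusted p 0.031) at the preset. With an estimated correlation these had adjusted p = 0.45 and adjusted p = 0.55. The erythrocyte mean shrank to -0.22 without Vehicle 3. With all libraries, proliferation genes had a mean of 0.14, with Pcna at 0.38, Mcm3 at 0.20 and Ccnb1 at 0.24. Hypoxia and glycolysis genes had a mean of 0.21, with 13 of 13 members above 0, among them Vegfa at 0.39, Ndrg1 at 0.41 and Slc2a1 at 0.29. The p53 and DNA damage mean was -0.02, with Plk3 at -0.43, Btg2 at 0.33 and Zmat3 at 0.14. Immediate early and heat shock genes had a mean of 0.10, with Egr1 at 0.39, Hsph1 at 0.35 and Hspa1a at 0.29. Erythrocyte genes had a mean of -0.74, with Hba-a1 at -0.82, Alas2 at -0.89 and Hbb-bt at -0.73. Over all genes and adjusted over the list alone, 0 members of these 5 lists were called. Too few members were measured to test mast cells (2 of 8, Hdc at 0.33 and Kit at 0.05), cytotoxic and NK cells (1 of 12, Ccl5 at 0.30), skeletal muscle (1 of 8, Actn3 at 0.43) and mitochondrially encoded genes (0 of 9).

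Transcripts of pancreatic acinar cells, which make digestive enzymes, stood out in 1 library of each group. The mean log2 level of the acinar list was 9.04 in Vehicle 2 and 9.19 in AZD7507 2, and lay between -3.58 and -0.28 in the other 4 libraries. These genes made up 2.46% and 2.71% of the summed RPKM in both libraries, and at most 0.0053% in the others. The list did not pass between the groups (mean 0.63, camera adjusted p 0.84, 0 calls over all genes or adjusted over the list alone), with Prss2 at 1.21, Ctrb1 at 0.93 and Cela3b at 0.80. With these genes so uneven within each group its mean ran from -2.87 without AZD7507 2 to 4.37 without Vehicle 2, and in the latter it passed at the preset correlation (adjusted p 0.047; adjusted p = 0.67 with an estimated correlation). The first principal component, with 48.1% of the variance, set both libraries apart, and the second, with 24.7%, separated the treatment groups. Without both libraries 13 genes fell and 1 rose. The macrophage list then had a mean of -1.66 (camera adjusted p 8.9e-17 at the preset and 0.67 with an estimated correlation). With so few libraries left, camera with an estimated correlation could hardly pass, so that loss decides nothing. With the acinar score as covariate 187 genes fell and 16 rose, with the 55 and 3 of the fit without it among them.

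**Figure D3:**
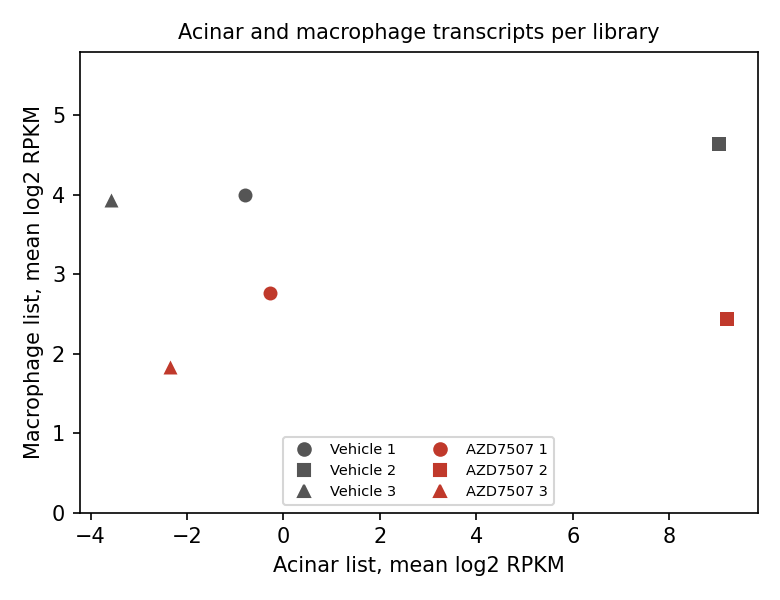
Mean log2 RPKM of the macrophage list against that of the acinar list in each library, with vehicle in grey and AZD7507 in red. Vehicle 2 and AZD7507 2 lie at acinar values of 9.04 and 9.19, and the vehicle libraries lie above the AZD7507 libraries on the macrophage axis.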

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

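The acinar covariate, the fit without both acinar-rich libraries and the estimated correlation in these and in each fit that left out 1 library were chosen after seeing the data. The other alternatives were planned. The macrophage list kept its direction in all 21 alternatives, with means from -2.06 to -1.59, and lost its call in 10, those with an estimated correlation (adjusted p 0.39 with all libraries) and fry (0.052). The cause of most changes was not tested; leaving out libraries lowers the number of samples. Genes that rose numbered 3 and changed to 1 with a constant prior, 14 with array weights, 16 with the covariate, 1 without both acinar-rich libraries and 0 in each fit that left out 1 library. Genes that fell numbered 55 and changed to 143 with array weights, 187 with the covariate, 13 without both acinar-rich libraries and 0 to 14 with 1 library left out. With a constant prior 43 genes fell, of which only 33 were among the 55. Of the 55, 12 were among the 13, and all 55 were among the 143 and among the 187. Lists that rose numbered 1, with 0 under the estimated correlation, 0 under fry, 3 with the covariate, 5 without both acinar-rich libraries, and 0 to 3 with 1 library left out. Lists that fell numbered 5, with 0 under the estimated correlation, 0 under fry, 3 without both acinar-rich libraries, and 4 to 8 with 1 library left out, the 8 without Vehicle 1. Csf1r kept its sign, from -2.83 to -2.30, and lost its call in 8 of 15 alternatives, with adjusted p between 0.0040 and 0.15 over all of them. With the same sign, 135 values of named genes and 67 of lists lost a call under an alternative, and 13 and 22 gained one. With the covariate the lists that gained a call were B and plasma cells, epithelial, mesothelium and resident-type macrophages (camera adjusted p 0.027, 0.0062, 0.0090 and 0.025). Without both acinar-rich libraries they were immediate early genes (0.039), hypoxia, proliferation and, with a turned sign, matrix remodelling (0.024). All of these calls were at the preset correlation. With an estimated correlation 0 lists rose and 0 fell with the covariate and without both acinar-rich libraries. The same held in each fit that left out 1 library. The macrophage list then had camera adjusted p from 0.36 to 0.67. Fewer libraries or a covariate leave camera with an estimated correlation little room to pass, so these losses decide little.

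Among values that did not pass, signs turned when 1 library was left out. The lowest and highest log2 differences were -0.060 and 0.96 for Actn3, -0.051 and 0.78 for Ccl5, -0.041 and 0.33 for Csf1, -1.91 and 0.012 for Ctsk, -0.093 and 0.70 for Hdc, -0.33 and 0.80 for Hspa1a, -0.31 and 0.34 for Kit, and -0.30 and 0.019 for Notch3. For the acinar genes they were -2.56 and 4.44 for Cela3b, -2.46 and 4.62 for Ctrb1 and -1.999 and 5.02 for Prss2. For list means they were -0.17 and 0.47 for adipocytes, -0.32 and 0.27 for recruitment factors, -0.052 and 0.18 for endothelium, -0.053 and 0.21 for immediate early genes, -0.26 and 0.22 for matrix remodelling, -0.45 and 0.075 for monocytes, -0.50 and 0.77 for neutrophils, -0.083 and 0.025 for p53, -2.87 and 4.37 for the acinar list, and -0.23 and 0.19 for smooth muscle. With 1 library left out and an estimated correlation the means are the same, and those of turned sign between these ends were -0.082 for adipocytes, 0.0084 for recruitment factors, -0.010 for immediate early genes, 0.089 and 0.097 for neutrophils, 0.016 and 0.020 for p53, -0.54 and -1.94 for the acinar list and -0.0084 for smooth muscle. Without both acinar-rich libraries signs turned for Kdr (-0.019), Kit (-0.21), recruitment factors (0.23), matrix remodelling (0.29, adjusted p 0.024), monocytes (0.092), neutrophils (0.88) and p53 (0.057). Array weights gave -0.23 for Kit. The minimum mean level of 0 gave -0.092 for adipocytes, 0.081 for checkpoints and -0.060 for smooth muscle, and the pseudocount of 1 gave -0.040 for smooth muscle. The covariate sets acinar genes to 0 by construction, so they have no value there. No scaling moved the median difference of all genes, 0.025, by over 0.1. The deposited medians were already 2.32 in each library, so this could hardly have come out otherwise. Depth is unknown, so its limit on low genes could not be assessed.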

Other observations

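Of the tests in this part, those of acinar tissue, of equal leukocyte loss, of equal loss of every macrophage transcript and of 1 kind of tissue were chosen only after the result was seen. The rules for reading the second acinar list, the liver list and the spread between both acinar-rich libraries were also changed after their values were seen.

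Some genes that bone-resorbing osteoclasts express were high in Vehicle 2. In that library Ctsk was at 6.45, Mmp9 at 5.94 and Acp5 at 5.62, while the highest of the other libraries lay lower by 3.52, 4.29 and 2.23. These 3 were picked after the library had been seen to stand apart. Of other osteoclast genes, Atp6v0d2, Nfatc1 and Tnfrsf11a exceeded the next library by 1.59, 1.03 and 1.02. Dcstamp, Itgb3 and Clcn7 exceeded it by only 0.28, 0.28 and 0.37. Tcirg1 and Calcr were higher in another library, their Vehicle 2 values less the highest other being -0.044 and -1.61. With the 3 picked genes included, Vehicle 2 was highest for 9 of 11 measured osteoclast genes, with a median excess of 1.02 over the 11. Of 4 measured bone matrix genes, Alpl was at 3.53 there, 1.34 above the highest other library, while Sp7 and Runx2 were about as high in AZD7507 2 and Col10a1 went the other way, its Vehicle 2 value less the highest other being -1.92.

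The macrophage list fell by a mean of 1.85 with AZD7507, a call lost with an estimated correlation (adjusted p = 0.39) and with fry (adjusted p = 0.052). Acinar tissue as the whole explanation is argued against by the mean of -1.66 without both acinar-rich libraries. Of 10000 lists matched on level, length and GC content, the 2.5th percentile was -0.097 and none (0) was as low. Values already adjusted for length and GC content, with like distributions in each library, keep such lists near 0. The matched lists thus show only that genes of like kind did not shift, and decide nothing on other effects of normalization. An equal loss of all leukocytes is argued against by the gap of -1.43 (SE 0.36) between the macrophage list and the pooled neutrophil, T cell and B cell lists. That pool of 20 genes, which includes Mmp9, itself changed by -0.42 (SE 0.42), so how far those leukocytes changed is not settled. On equal loss of every macrophage transcript, 2 fits were tried: the first, with the spread shared over all genes, called 0 of 18 members as deviating from the list's mean (smallest adjusted p 0.069, median SE 0.44), and the second, with the spread shared over the members and chosen after that result because subtracting the list score adds its spread to every gene, called 9 (median SE 0.17), from Cx3cr1 at -1.33 to Trem2 at 1.15 relative to the list. The second fit argues against equal loss. After subtraction 11 of 18 members had groups that did not overlap (61.1%, against 10% by chance for 1 gene). Subtraction ties the members to each other, so they are not 18 independent results and this share adds no separate support. It stays open as a hypothesis whether fewer macrophages, other cells that carry Cd68 or Trem2, or lower transcription per cell may account for the pattern.

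Acinar transcripts appeared in Vehicle 2 and AZD7507 2, in 9 of 9 measured genes. Whether 1 kind of tissue lies behind both is left open. The difference between both had an SD of 0.138 (log2) over the list. Its values, 8.48 to 9.87, lie near the maximum of 10.16 shared by all libraries, and whether that maximum limits their differences was not tested. Pancreas in the sampled piece is a candidate source, but the second acinar list decides nothing: 100% of its measured members were higher in both, yet that is 1 gene of 18, Nr5a2. Liver cannot be told apart, since 4 of 15 liver genes were measured and their median difference was 0.458 with an SD of 0.936. No biological explanation was tested, as no label names the site of a tumour.

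On chromosome 7 of GRCm38, 5 genes that fell lie within 250 kb. E230029C05Rik (89980723 to 90049069) changed by -2.14 and the models Gm44860 and Gm44861 inside it by -2.57 and -2.51, while Gm45220 and Gm45221, in introns of Picalm (90130213 to 90213465), changed by -0.96 and -0.79. In 10000 draws of as many genes 0% held so dense a window, which argues against chance clustering of separate genes, although models on the same strand inside another gene may share its reads. Picalm reads, falling as that gene did (-0.54, without passing), are argued against for Gm45220 and Gm45221, whose mean difference less that of Picalm was -0.34 (SE 0.095), though these were looked at because they fell. The other 2 models in its introns lay within 2 SE of Picalm, with Gm45222 at -0.18 (SE 0.12) and Gm45223 at -0.064 (SE 0.091) relative to it and all 4 at -0.23 (SE 0.072), and whether unspliced Picalm RNA followed another course was not tested.

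With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real split gave 58 genes and the highest other split 0, so 1 of the 10 splits gave as many. For gene lists with the preset correlation of 0.01 the real split gave 6 and the highest other 16, and 9 of the 10 splits gave as many. List calls at the preset therefore do not set the treatment apart from other splits. The estimated correlation between members was 0.75 for the macrophage list, 0.76 for MHC class II and 0.38 for interferon response. It was 0.24 for T cells, 0.068 for complement and 0.014 for the CSF1R axis. For the CSF1R axis this is near the preset of 0.01, yet its unadjusted camera p went from 0.00028 to 0.023. Correlation between members therefore does not account for that lost call. Why other splits gave so many calls was not tested. The macrophage list's mean difference had a size of 1.85 in the real split and at most 1.07 in the others.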
